A study of Homo sapiens with 16 samples.

How the data were processed

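Gene expression was measured in a reconstructed human epidermis model, a commercial culture of stratified keratinocytes, 16 h after a narrow line across the tissue had been exposed to 0.5 Gy of alpha-particles or sham-treated (0 Gy). RNA came from tissue that lay 125 to 625 µm from the line (near) or 625 to 1125 µm from it (far), outside the exposed line, so the comparison concerns bystander tissue. The labels give 4 groups of 4 arrays, named by dose, distance and replicate number. The design text speaks of 3 independent experiments and 3 tissue fragments per point, and the labels do not say which arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The free-text descriptions of the samples contradict the titles, the treatment labels and the series text on the kind of radiation and the time, and were not used.

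Each sample was 1 Cy3 array of a whole-genome Agilent design. Per the file headers and the submitters' processing notes, the authors' spot intensity values come from Agilent Feature Extraction 9.1.3.1, with background subtraction and detrending within each array. The headers also place the 16 arrays on 4 slides of 4 arrays, scanned on 2 days. Slide 1 held 0 Gy replicates 1 and 2 of both distances and was the slide scanned on the other day. Slide 2 held 0.5 Gy replicates 1 and 2, slide 3 held 0 Gy replicates 3 and 4, and slide 4 held 0.5 Gy replicates 3 and 4. Each slide therefore held 1 dose and both distances. The authors' deposited series table holds log2 values. Set against the spot intensities, each of its columns equals log2 of the processed signal plus 1 shift per array, to within 0.01, for 98.7% to 99.6% of the probes filled in. Its column medians ran from 5.81 to 7.91, no centring of genes was seen, and the rule behind the shifts and the empty cells stays unknown.

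Of 41000 probes, 40897 remained without Y-linked genes and the X-inactivation transcripts. Probe names were taken through RefSeq accessions for 25398 probes, through a current symbol for 2510 and through an older symbol for 789, and the file's own name was kept for 12303. Spots of a probe were averaged without outlier spots. Intensities were divided by each array's 75th percentile over the 7197 probes well above background on all arrays, because fewer than 50% of the probes were detected on the arrays of slide 3. A common floor of 0.0411 on the scaled signal, the highest detection limit of any array, was applied before log2 was taken (log2 of the floor, −4.60). A probe was kept where it was well above background on every array of at least 1 group, and each gene was represented by its kept probe of highest mean. Log2 changes of genes near the floor are therefore understated, and arrays at the floor show no spread. No genome was used. Genes of the fixed lists with no probe found were CMPK2, AKR1C2, FLG2, SPRR2A, SPRR2B, HRNR, SBSN and HSPA1B. Other members had no kept probe and were not tested, so counts of list members are of those kept. For example, 7 of 32 interferon, 9 of 30 mitotic, 15 of 30 replication, 2 of 14 immune and 2 of 12 melanocyte genes were kept.

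limma 3.58.1 in R 4.3.3 was fitted to all 16 arrays with 4 group means (lmFit and eBayes), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were the dose at each distance, the dose over both distances, the difference of the dose effect between distances, and far minus near at each dose. The 25 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule took, for each dose contrast, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between doses, the 3 genes of smallest p for each distance contrast with too few calls, up to 4 members of each list by p over both distances, and 17 sentinel genes. Of the list members so chosen, the report gives those that were called and the sentinels, while the checks of single arrays and of alternatives ran on all of them. Some genes that the rule or the lists contain are not reported here and were left out of these checks, although fits, counts of genes and list tests include them. Lists were tested with camera (preset correlation 0.01), adjusted over the 25 lists and the 3 dose contrasts. The list tests of the 3 distance contrasts were adjusted as a family of their own, which was not planned and was chosen after the single-gene results had been seen. An estimated correlation, and fry, which asks whether the genes of a list move 1 way on balance, were computed beside each. List means per array were compared by a two-sided exact permutation test.

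Slide was used as a random block for the dose contrasts, where it cannot be a fixed one, and as a fixed block for the distance contrasts, which lie within slides. The fits were tested on simulated data of 9236 genes with the measured spread. Over both distances, 13.6%, 67.7% and 89.9% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 1.52%, 40.0% and 68.1% in the near contrast. These dose runs gave the arrays of a slide no shared effect, whereas slide as a random block estimated a correlation of 0.694 within slides. They therefore do not show the recovery where arrays of 1 dose share slides. With the spread within group and slide, and slide as a fixed block, recovery was 31.8%, 73.8% and 88.4% for the distance at 0.5 Gy. It was 7.58%, 53.8% and 75.4% for the interaction. A list shifted by 0.2 between distances at 0.5 Gy was found in 9 of 10 runs, with 1 other list called. Simulated genes varied independently, so these runs do not test false list calls where the genes of a list are correlated. Alternatives covered background correction (normexp with offset 50), scaling, filters, the choice of probe, slide, tissue and replicate blocks, subsets of replicates, the series table, and leaving out each array. The tissue block took near and far arrays of the same dose and replicate number as 1 tissue, which the labels do not state. The number of arrays and slides limits the precision of every value.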

Results

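The 16 arrays measured bystander tissue of a reconstructed human epidermis model, with 4 arrays each for 0 Gy near, 0 Gy far, 0.5 Gy near and 0.5 Gy far, near being 125 to 625 µm and far 625 to 1125 µm from the exposed line. The signal differed mostly by slide. On slide 1 (0 Gy) 70.0% to 72.1% of the probes were well above background, on slide 3 (0 Gy) 21.1% to 28.6%, on slide 2 (0.5 Gy) 52.4% to 63.8% and on slide 4 (0.5 Gy) 58.5% to 61.9%. The 75th percentile of the processed signal was 8438 to 10345 on slide 1 and 185 to 330 on slide 3, against 1807 to 2634 on slide 2 and 2163 to 2534 on slide 4. After scaling, 6827 of 9806 genes differed between the bright (slide 1) and the dim (slide 3) 0 Gy slide in limma, 3961 higher on the bright slide and 2866 lower, with an SD of the differences across genes of 1.27 on the log2 scale. Between the 0.5 Gy slides limma called 0 genes (929 at an unadjusted p under 0.05) and the SD was 0.22, while the SD of the dose difference was 0.44. Arrays of 1 group on 1 slide differed by less than the noise of repeated spots in both pairs of 0 Gy near and in 1 of the 2 pairs each of 0 Gy far and 0.5 Gy far. Near and far arrays of 1 slide did so in 8 of 16 pairs. Across the slides of 1 dose, 1 of 16 pairs within a group and 1 of 16 near and far pairs did so. The ratio therefore does not show which arrays came from 1 sample. Counts with each group's arrays on a slide averaged (slide means counted once) are given beside those of the fit to 16 arrays. The means were taken for each distance, so over both distances each slide still entered with a near and a far mean.

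**Figure D1:**
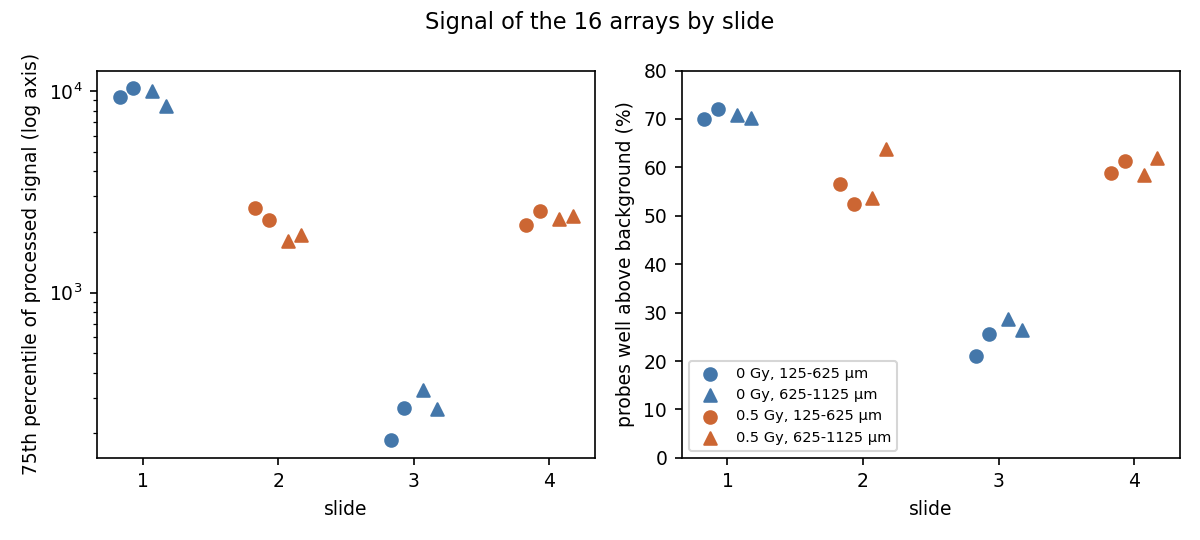
Signal of each array by slide. The left panel gives the 75th percentile of the processed signal over probes well above background on all arrays (arbitrary units, log axis), the right panel the percentage of probes well above background, with single arrays as points, coloured by dose and shaped by distance. The 4 arrays of slide 3 lie between 185 and 330, below all others.

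The comparison at the near strip asked how tissue next to the exposed line differed between 0.5 Gy and sham treatment. The largest falls were in STRAP (−1.84 ± 0.18, log2 difference ± SE, 4 arrays against 4), DGCR2 (−1.84 ± 0.39), SKP1, a component of SCF ubiquitin ligases (−1.79 ± 0.13), LMNB2, which encodes lamin B2 (−1.67 ± 0.13), and ACTG1, which encodes gamma-actin (−1.62 ± 0.22). KLHL17 (−1.51 ± 0.22), CLUH (−1.45 ± 0.23), CDC42EP4 (−1.45 ± 0.23), CLPS (−1.38 ± 0.23), IRGC (−1.36 ± 0.20), ELF5 (−1.35 ± 0.21) and RARA, a retinoic acid receptor (−1.26 ± 0.21), fell by less. The largest rises were in MACF1, a cytoskeletal linker (3.30 ± 0.77), POU3F3 (1.91 ± 0.24), RASAL2 (1.84 ± 0.44), CHD6, a chromatin remodeller (1.79 ± 0.17), TMCC2 (1.65 ± 0.26), ASPRV1, a protease of the upper epidermis (1.64 ± 0.18), and UGT8 (1.61 ± 0.19). JAKMIP3 (1.56 ± 0.28), CHMP4C (1.49 ± 0.31), SPPL2B (1.45 ± 0.27), GOLGA4 (1.44 ± 0.33) and PFKL (1.43 ± 0.30) rose as well. Of the near 0 Gy arrays, 2 of 4 were well above background for POU3F3, CHD6, UGT8 and PFKL and 3 of 4 for MACF1 and RASAL2, as were 2 of the 4 near 0.5 Gy arrays for LMNB2. The 0 Gy values of CHD6 and UGT8 and the 0.5 Gy values of LMNB2 lay at the floor at both distances, so their differences are lower bounds and their SE lacks the spread of 1 dose.

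In all, limma called 183 of 9837 genes at the near strip, 142 higher and 41 lower at 0.5 Gy. With slide as a random block 2 genes stayed called, SKP1 and LMNB2. With slide means counted once 0 were called (550 at an unadjusted p under 0.05), with normexp 0 (707), and with only the arrays compared 6. Leaving out 1 array took the count to 79 and 96 (0 Gy near replicates 1 and 2), to 60, 78 and 59 (0.5 Gy near replicates 1, 2 and 3) and to 116 (0.5 Gy far replicate 4). Of the calls 77.6% were higher, against 51.0% with quantile normalization, 43.3% with the series table and 25.4% with the 75th percentile over all probes.

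At the far strip the falls were led by STRN3 (−2.00 ± 0.30), SKP1 (−1.91 ± 0.14), DGCR2 (−1.90 ± 0.36), STRAP (−1.83 ± 0.18), ACTG1 (−1.82 ± 0.22) and LMNB2 (−1.74 ± 0.13). KLHL17 (−1.31 ± 0.22), CDC42EP4 (−1.25 ± 0.25), CYB561D1 (−1.23 ± 0.21), AKT2, a kinase of insulin and growth factor signalling (−1.22 ± 0.24), ANO8 (−1.21 ± 0.27) and NRN1 (−1.18 ± 0.18) also fell. The rises were led by SP3, a transcription factor (1.86 ± 0.41), POU3F3 (1.63 ± 0.24), POF1B, an actin-binding epithelial protein (1.54 ± 0.23), CHD6 (1.51 ± 0.17), SCARNA17 (1.47 ± 0.24) and SRD5A1, a steroid reductase (1.46 ± 0.29). SLC25A36 (1.42 ± 0.28), ASPRV1 (1.37 ± 0.18, but −0.34 with quantile normalization), FGD4 (1.36 ± 0.29), AKAP11 (1.34 ± 0.30), CHD8 (1.32 ± 0.21) and RESF1 (1.30 ± 0.20) rose too. Of the far 0 Gy arrays, 2 of 4 were well above background for POU3F3 and CHD6 and 3 of 4 for SLC25A36, FGD4 and RESF1, as were 3 of the 4 far 0.5 Gy arrays for LMNB2. ASPRV1 had no usable value on the dim 0 Gy slide and POF1B none on the bright one, so each rests on 1 slide of 0 Gy.

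At the far strip limma called 115 of 9832 genes, 85 higher and 30 lower. With slide as a random block 2 were called, again SKP1 and LMNB2, with slide means counted once 0 (313 at an unadjusted p under 0.05), with normexp 0 (317) and with only the arrays compared 12. With the replicate block 68 were called. Leaving out 1 array took the count to 29, 42 and 50 (0 Gy far replicates 1, 2 and 4), to 44, 34, 50 and 25 (0.5 Gy far replicates 1 to 4), to 67 (0 Gy near replicate 2), to 64 (0.5 Gy near replicate 3) and to 266 (0 Gy near replicate 3). Of the calls 73.9% were higher, against 58.0% with the array median, 36.2% with quantile normalization, 33.3% with the series table and 11.8% with the 75th percentile over all probes. The near and far calls shared 53 of the higher genes, where independent lists would share 1.23, and 23 of the lower ones, against 0.125. The near and far pieces lay on the same slides, so this overlap includes whatever the slides added to both.

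Over both distances the falls of largest size were DGCR2 (−1.87 ± 0.26), SKP1 (−1.85 ± 0.10), STRAP (−1.84 ± 0.13), ACTG1 (−1.72 ± 0.16), LMNB2 (−1.71 ± 0.09) and STRN3 (−1.61 ± 0.21), followed by KLHL17 (−1.41), CDC42EP4 (−1.35), IRGC (−1.27), SPANXA2-OT1 (−1.23), RARA (−1.22) and AKT2 (−1.21). The rises were LGR4, a receptor of stem and progenitor cells (1.78 ± 0.37), POU3F3 (1.77 ± 0.17), PRR7 (1.74 ± 0.49), CHD6 (1.65 ± 0.12), SP3 (1.55 ± 0.29), ASPRV1 (1.50 ± 0.13) and POF1B (1.46 ± 0.16), then CFAP97 (1.44), UGT8 (1.37), KAT2B, a histone acetyltransferase (1.36), SDF2L1 (1.35) and CHMP4C (1.34). SKP1 at 0.5 Gy differed by −1.91 from the bright and by −1.80 from the dim 0 Gy slide, and LMNB2 by −1.83 and −1.58. For SKP1, STRAP and ACTG1 the dose difference of another probe of the same gene reached 0.23, 0.37 and 0.21, and for KAT2B, ELF5 and POF1B another probe gave −0.36, 0.03 and −0.63, while the remaining probe of POF1B gave 1.16 and was called. The other probes of LGR4, PRR7 and RARA gave 0.02, 0.36 and −0.10, and with the mean of its probes SKP1 differed by −0.54. The 2 kept probes of MACF1, the largest rise at the near strip, gave 2.72 and 0.75 over both distances, and 1 of them was called.

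**Figure D2:**
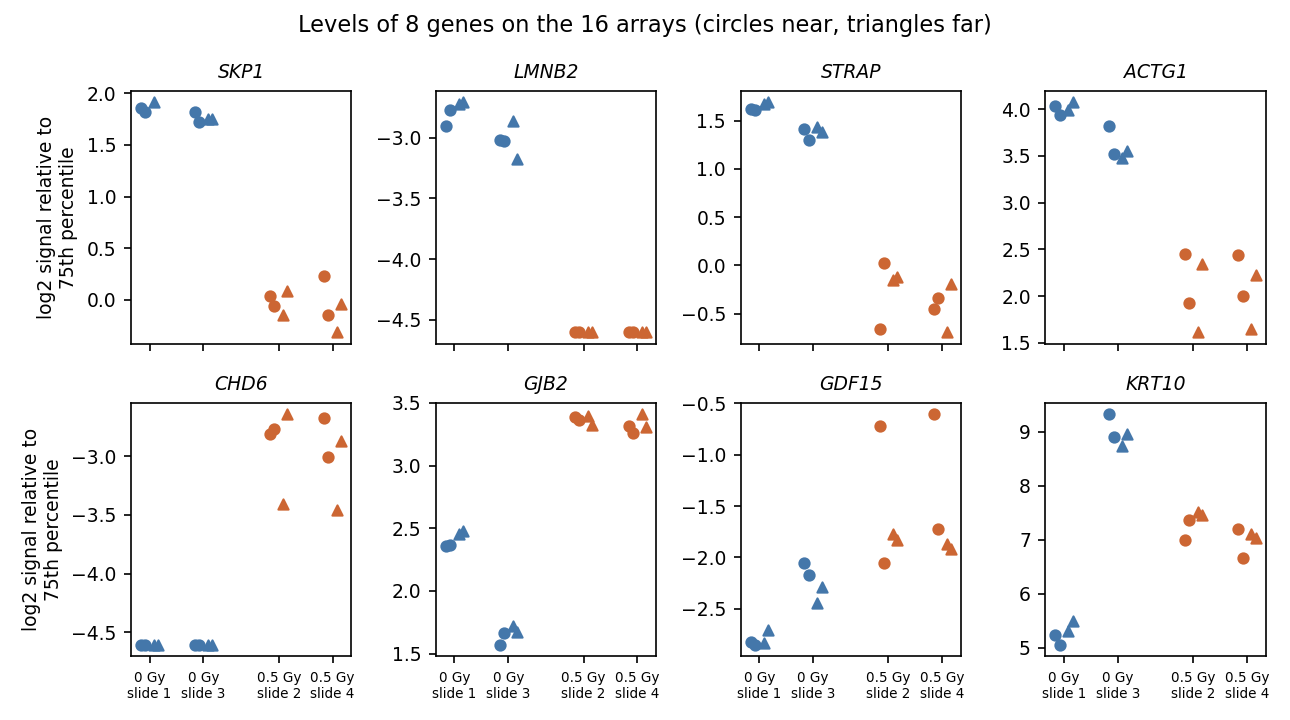
Levels of 8 genes on each of the 16 arrays, as log2 signal relative to the array's 75th percentile, by slide. Circles are near and triangles far arrays, blue is 0 Gy and orange 0.5 Gy, and values at −4.60 lie at the floor. SKP1 and LMNB2 were lower on both 0.5 Gy slides than on either 0 Gy slide, while KRT10 at 0.5 Gy differed by 1.89 from the bright and by −1.81 from the dim 0 Gy slide.

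Of the sentinel genes of DNA damage and inflammation 1 was called over both distances. CDKN1A, the p53-induced cell cycle inhibitor, differed by −0.02 ± 0.15, PTGS2 (cyclooxygenase) by 0.11 ± 0.13, IL1B by 0.12 ± 0.10, MMP1 by −0.31 ± 0.14 and HMOX1 by 0.55 ± 0.25, none of them called. Some of these values average opposed differences, since CDKN1A at 0.5 Gy differed by 0.33 from the bright and by −0.36 from the dim 0 Gy slide, PTGS2 by −0.16 and 0.37, and HMOX1 by −0.07 and 1.18. Of the 8 0 Gy arrays, PTGS2 was well above background on 5 and IL1B on 4. MDM2, MMP3, CXCL8 and MKI67 were not well above background on every array of any group. GDF15, a stress-induced cytokine, rose by 0.96 ± 0.21 (limma adjusted p = 0.0118). Its level was −0.72 and −0.61 on 0.5 Gy near replicates 1 and 3, but −2.06 and −1.72 on replicates 2 and 4. On 0 Gy near replicate 3 it was −2.05. The 0 Gy slides differed by −0.56 (bright minus dim, not called), so the rise was smaller against the dim slide. Of the differentiation sentinels, KRT1 (0.57 ± 0.54), KRT10 (0.04 ± 0.71), KRT14 (0.24 ± 0.18), KRT16 (−0.17 ± 0.12), LORICRIN (0.40 ± 0.22) and FLG (0.54 ± 0.17) were not called.

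Over both distances limma called 1026 of 9830 genes, 862 higher and 164 lower at 0.5 Gy. With slide as a random block 2 genes were called, SKP1 and LMNB2. In simulated slide effects of 1 common spread without a dose effect, this fit still called 132 to 240 genes. With slide means counted once per distance 0 were called (985 at an unadjusted p under 0.05, 491.5 expected by chance). This fit takes the near and far means of a slide as independent, so the 985 is not a count at the level of slides. With normexp 0 were called (1402), and with tissue as a random block 132. Without 0.5 Gy far replicate 2 the count was 658 and without 0.5 Gy near replicate 3 it was 664. Of the calls 84.0% were higher, against 60.8% with quantile normalization, 51.9% with the series table and 26.7% with the 75th percentile over all probes, which moved the median difference of all genes from 0.15 to −0.11. Normexp moved that median to −0.30. Replicates 1 and 2 alone gave 6036 genes and replicates 3 and 4 alone 3633. Across genes, which are not independent replicates, the dose differences of these pairs of slides correlated at −0.392, and of 2384 genes called in both 472 had the same direction (393 up, 79 down) and 1912 the opposite. The same correlation was −0.271 at the near strip and −0.471 at the far strip, where 137 of 1008 and 113 of 1007 genes called in both had the same direction.

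**Figure D3:**
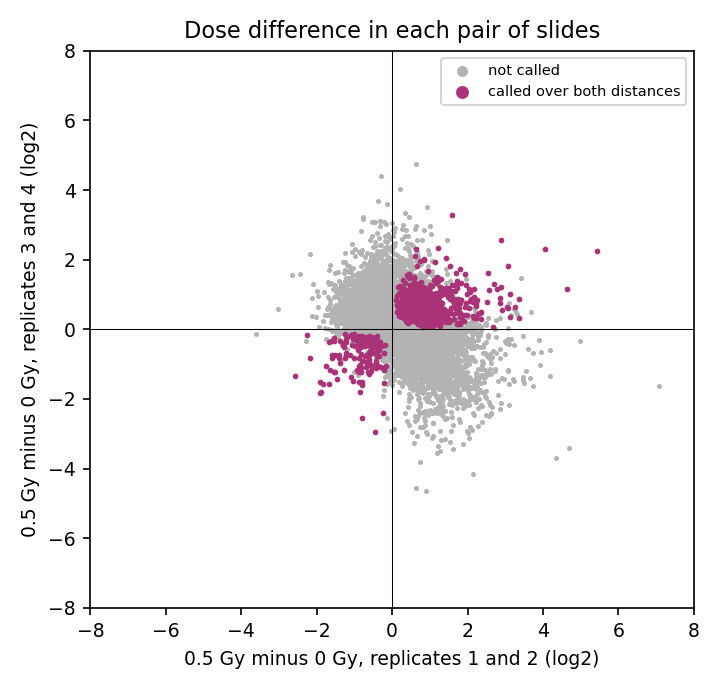
Dose difference of each gene over both distances (0.5 Gy minus 0 Gy, log2) in replicates 1 and 2 (horizontal axis) and in replicates 3 and 4 (vertical axis). Each point is a gene, and coloured points were called with all 16 arrays. The points run downwards, with a correlation across genes of −0.392.

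In camera with the preset correlation, DNA replication was the list that shifted with dose. At the near strip it lay below other genes (median −0.39, 12 of 15 members lower, camera adjusted p = 0.00403), as it did over both distances (median −0.26, adjusted p = 0.0185). With an estimated correlation the adjusted p was 0.615 in both contrasts, and in fry it was 0.0980 and 0.122. Over both distances MCM7, a replicative helicase subunit (−0.56 ± 0.13), UHRF1 (−0.61 ± 0.18) and CDC45 (−0.74 ± 0.22) fell, and PCNA, the replication clamp, rose (0.73 ± 0.20). In all 4 of its members fell, 1 rose and 10 did not pass, and 5 were called adjusted over the list alone. The camera adjusted p over both distances was 0.118 with slide as a random block. At the far strip the list was not called (median −0.06, adjusted p = 0.274). The near shift was not called within either pair of slides (medians −0.44 and −0.27, adjusted p = 0.360 and 0.777) or over probes well above background on all arrays (0.198). Over both distances the median was −0.48 in replicates 1 and 2 (adjusted p = 0.410), but 0.00780 in replicates 3 and 4 (0.911) and −0.06 without the bright slide (0.821).

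No other list passed in camera between the doses, with adjusted p from 0.287 to 0.997 over both distances. In fry, which does not compare a list with other genes, apoptosis regulators (adjusted p = 0.00870) and wound keratins and alarmins (0.0261) passed over both distances. At the near strip fry also called cornified envelope (0.0290), suprabasal (0.0366), wound (0.0286) and apoptosis genes (0.0261), and at the far strip apoptosis (0.0290) and ribosomal protein genes (0.0261), all with medians above 0. The median of all genes was itself 0.13 near, 0.15 far and 0.15 over both distances. With the 75th percentile over all probes it was −0.11, −0.13 and −0.11. Fry tests against 0, so these calls include that offset, which depends on the scaling. Over all genes 862 of 9830 rose over both distances, against which the following counts of members are to be read. Of the p53 targets 4 of 21 rose over both distances, GDF15, CCNG1 (0.72 ± 0.19), TRIAP1 (0.40 ± 0.11) and BBC3 (0.68 ± 0.19), and 6 were called adjusted over the list alone. Of the apoptosis regulators 3 of 16 rose, among them BBC3 and HRK (0.87 ± 0.25), with 5 called adjusted over the list alone. Of the inflammatory cytokine list 2 of 13 rose, CXCL5 (0.68 ± 0.18) and LCN2 (0.58 ± 0.16), and 2 adjusted over the list alone. Of the suprabasal list 2 of 14 rose, DSC1, a desmosomal cadherin (0.50 ± 0.10), and CDH1, which encodes E-cadherin (0.62 ± 0.15), and 2 adjusted over the list alone. With normexp background correction the values of CCNG1 (−0.29), TRIAP1 (−0.07), HRK (−0.01) and CXCL5 (−0.13) turned below 0. The offset of that method, which lifts faint genes on the dim 0 Gy slide, may add to this. Of the 8 0 Gy arrays, CCNG1 was well above background on 4 and HRK on 5. The median and the test differed in sign for the lists of mitosis, double-strand break repair, interferon response, antioxidant, basal, cholesterol, immediate early and hypoxia genes, with medians above 0 and a test pointing down relative to all genes.

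Single members were called in further lists, whose sizes count only the members kept after the detection filter. Over all genes 862 of 9830 rose and 164 fell, so 1 call does not by itself set such a list apart. GJB2, which encodes the gap junction protein connexin 26, rose by 1.31 ± 0.16 (adjusted p = 3.65e-04) and lay 0.93 above the bright and 1.69 above the dim 0 Gy slide, while GJA1 (1.30 ± 0.57) did not pass, so 1 of 6 gap junction genes was called. Without 0 Gy near replicate 3 GJA1 differed by 0.69 and was called. In the lists of 16 basal, 20 wound, 18 antioxidant, 12 TGF-beta, 16 immediate early, 30 oxidative phosphorylation and 2 melanocyte genes, 1 gene each rose, namely ITGA6 (0.50 ± 0.15), SERPINB4 (0.48 ± 0.13), AKR1C1 (0.67 ± 0.19), ID2 (0.58 ± 0.14, but −0.03 with normexp), JUN (0.91 ± 0.24), SDHD (0.45 ± 0.08) and MITF (0.81 ± 0.23). Adjusted over the list alone, 1 gene each was called in the gap junction, TGF-beta, immediate early, oxidative phosphorylation and melanocyte lists and 0 in the basal, wound and antioxidant lists. In the lists of 9 mitotic, 11 matrix protease and 22 cholesterol synthesis genes, 1 gene each fell, namely PRC1 (−0.73 ± 0.18), ADAM8 (−0.60 ± 0.18) and CYP51A1 (−0.41 ± 0.12). Adjusted over the list alone, the counts were 1 in mitosis, 1 in matrix proteases and 0 in cholesterol synthesis. No member passed in the lists of 7 interferon, 32 cornified envelope, 22 heat shock and unfolded protein, 14 hypoxia, 31 ribosomal, 4 fibroblast, 2 endothelial and 2 immune cell genes, nor adjusted over the list alone except 1 endothelial gene. Other probes lay on the other side of 0 for BBC3 (−0.11), MITF (−0.16) and CYP51A1 (0.22). The marker lists of other cell types had a median difference between the 0 Gy slides (bright minus dim, not tested by list) of −1.26 for melanocyte, −0.93 for fibroblast, 0.35 for endothelial and −3.67 for immune cell genes.

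The 2 distances within a dose lay on the same slides, so the difference between them does not carry the differences between slides. The spread it is tested against in the fit without a slide block does. At 0.5 Gy, the list of cornified envelope and late differentiation genes was lower in the far than in the near strip (median −0.15, 27 of 32 members lower, camera adjusted p = 1.69e-06), and so were p53 targets (median −0.14, 19 of 21 lower, adjusted p = 1.55e-04). Mitotic genes were higher in the far strip (median 0.40, 8 of 9 members, adjusted p = 8.93e-04), as were DNA replication genes (median 0.23, 14 of 15, adjusted p = 0.0267) and ribosomal protein genes (median 0.13, 27 of 31, adjusted p = 0.0460). With an estimated correlation the adjusted p was 0.0116 for the cornified genes, and it was 0.255, 0.111, 0.581 and 0.264 for p53 targets, mitosis, replication and ribosomal proteins, so only the cornified call held. Among members chosen after their values were seen, with slide as a fixed block, the far minus near difference was −0.31 ± 0.08 for IVL (involucrin), −0.37 ± 0.09 for CDSN (corneodesmosin), −0.74 ± 0.23 for RPTN (repetin) and −0.35 ± 0.09 for CDKN1A. It was 1.06 ± 0.20 for UBE2C, a ubiquitin-conjugating enzyme of mitosis, 0.49 ± 0.21 for BIRC5 (survivin), 0.63 ± 0.24 for MCM6 and 0.33 ± 0.11 for RPLP1. None of these genes passed by itself over all genes tested.

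With slide as a fixed block the camera adjusted p for far minus near at 0.5 Gy was 4.27e-09 for the cornified genes, 3.00e-05 for p53 targets, 0.00102 for mitosis, 0.0956 for DNA replication and 0.00275 for ribosomal proteins, and the adjusted p with an estimated correlation was 0.186, 0.118, 0.246, 0.580 and 0.580, so that none of the 5 calls held in camera. Fry with this block called mitosis (adjusted p = 0.0149), p53 targets (0.0444) and ribosomal proteins (0.0444) and not cornified or replication genes (0.0967 for both), and without the block it called none of the 5. Adjusted over the list alone, 2 mitotic, 2 cornified, 1 p53 target, 0 replication and 0 ribosomal genes were called with this block, and without it 1 mitotic gene and 0 of the other 4 lists. The list means differed in the same direction on slides 2 and 4, by −0.19 and −0.19 for cornified genes, −0.12 and −0.17 for p53 targets, 0.46 and 0.31 for mitosis, 0.27 and 0.28 for replication and 0.16 and 0.13 for ribosomal proteins. The two-sided exact permutation p over the 8 arrays was 0.0571, 0.0857, 0.0286, 0.0571 and 0.0286, where 0.0286 is the smallest such a comparison allows. Each was 0.357 after adjustment over the 25 lists at both doses, which a list by itself could not pass even at that smallest p.

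**Figure D4:**
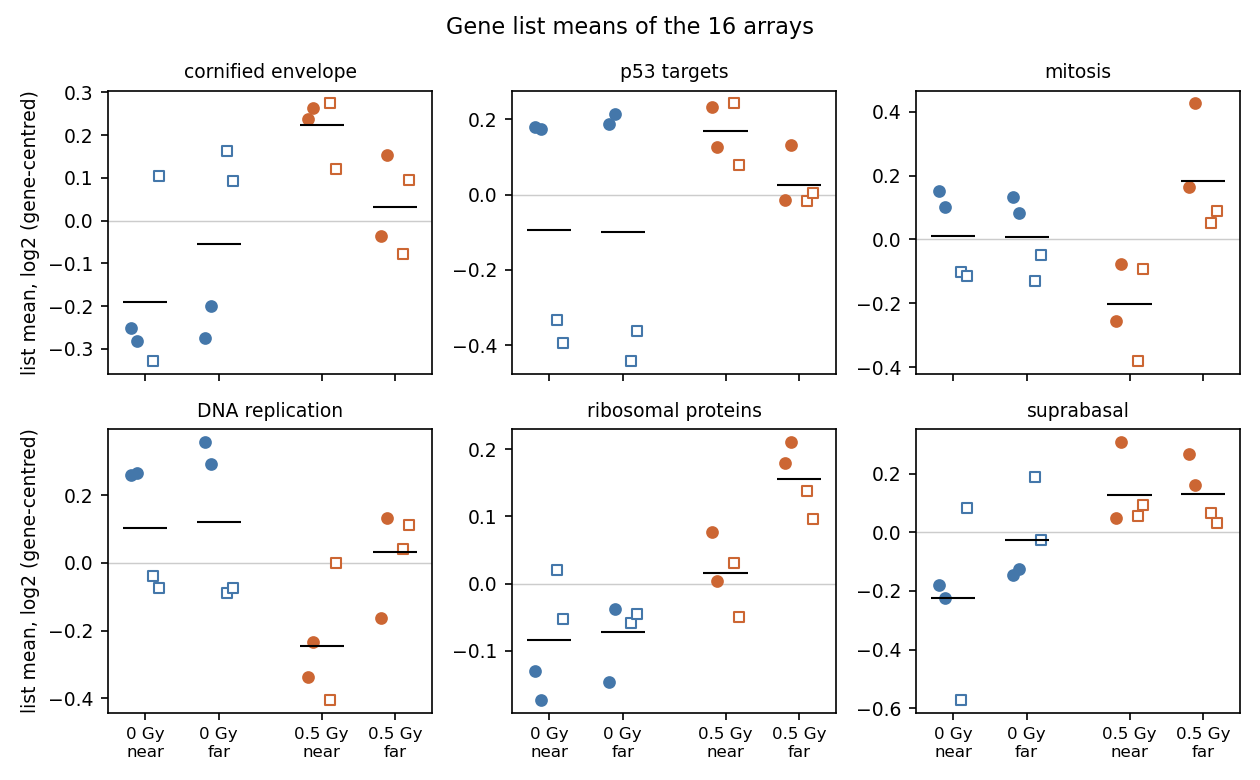
Means of 6 gene lists on each of the 16 arrays (log2, each gene centred on its mean). Circles are slides 1 and 2, open squares slides 3 and 4, blue is 0 Gy and orange 0.5 Gy, and lines are group means over 4 arrays. At 0.5 Gy the far arrays lie above the near arrays for mitosis and ribosomal proteins, with far minus near differences of 0.39 and 0.14.

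Without a single array, the calls of the cornified, p53 and mitosis lists at 0.5 Gy held in all 16 cases, with the highest adjusted p at 3.03e-04, 0.00824 and 0.0237. The 0 Gy arrays enter this contrast only through the shared spread, so the cases without a 0 Gy array leave the differences unchanged and test little. On 0.5 Gy near replicates 1 and 3 the p53 mean was 0.23 and 0.24 and the mitosis mean −0.26 and −0.38. On replicates 2 and 4 they were 0.13 and 0.08, and −0.08 and −0.09. The p53 and mitosis differences therefore rest more on 2 of the 4 near arrays. DNA replication lost its call without 0.5 Gy near replicate 3 (adjusted p = 0.285) and without 0.5 Gy far replicates 2 (0.0703), 3 (0.123) and 4 (0.176), and ribosomal proteins in 10 of the 16 cases (highest 0.405). Replication was also not called without a filter on dim probes (0.0770), over probes well above background on all arrays (0.235), with only the arrays compared (0.0507) or in replicates 1 and 2 (0.744). Its medians there were 0.18, 0.13, 0.23 and 0.25. Ribosomal proteins were not called with the array median (0.0654), the mean of a gene's probes (0.214), the pair of slides as a fixed block (0.0700), the replicate block (0.0953), the series table (0.371), the lowest floor (0.268), slide means counted once (0.0990) or in replicates 1 and 2 (0.329). Mitosis was not called with normexp (0.0951), with quantile normalization (0.0882) or in replicates 1 and 2 alone (0.134). Its medians there were 0.15, 0.32 and 0.40. The other 20 lists were not called between distances at 0.5 Gy, the nearest being hypoxia and glycolysis (adjusted p = 0.125), and suprabasal genes had a median of −0.03 (adjusted p = 0.459).

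At 0 Gy none of the 25 lists was called between distances, and limma called 0 of 9841 genes (40 at an unadjusted p under 0.05, 249 with slide as a fixed block). About 492 would reach that p by chance. The fit without a block counts differences between slides as spread, so its 0 calls do not show that distance had no effect. The 3 genes of smallest p were RABEP1 (−0.63 ± 0.15, far minus near), SCARF2 (−0.66 ± 0.21) and SCGB3A2 (−0.59 ± 0.20). The cornified list had a median of 0.03 and the p53 targets one of −0.02. The cornified list mean was higher far than near by 0.03 on the bright and by 0.24 on the dim 0 Gy slide (two-sided exact permutation p = 0.286). On the dim slide it was −0.33 on near replicate 3 and 0.10 on near replicate 4. The difference of the dose effect between distances, given below, also carries these 0 Gy values. At 0.5 Gy limma called 0 of 9830 genes (196 at an unadjusted p under 0.05, 960 with slide as a fixed block, 491.5 expected by chance). The smallest p were those of TMCC2 (−1.61 ± 0.26), JAKMIP3 (−1.36 ± 0.28) and OIP5 (1.20 ± 0.29).

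The difference of the dose effect between distances was tested directly. The lists called were cornified envelope (median −0.20, adjusted p = 1.44e-04, and adjusted p = 0.0212 with an estimated correlation but 0.246 with slide as a fixed block as well), mitosis (0.38, adjusted p = 0.00344, and 0.118 estimated), ribosomal proteins (0.14, adjusted p = 0.0160, and 0.255 estimated) and DNA replication (0.21, adjusted p = 0.0355, and 0.590 estimated). The p53 targets were not called (−0.15, adjusted p = 0.122). They passed in some settings, among them slide as a fixed block (adjusted p = 0.0198, and 0.305 with an estimated correlation), and without 0.5 Gy near replicate 2 or 0 Gy far replicate 3 (lowest 0.00765). With slide as a fixed block DNA replication lost its call (adjusted p = 0.186). Fry called no list for this difference. Mitosis lost its call without 0 Gy near replicate 1 (adjusted p = 0.0678), with quantile normalization (0.0851), in replicates 1 and 2 (0.125), in replicates 3 and 4 (0.196) and, just past the threshold, with the lowest floor, while the cornified call held without each array (highest 0.0449). The calls of DNA replication and ribosomal proteins were lost without 1 array in 9 and 5 of the 16 cases, and in other settings with adjusted p up to 0.749 and 0.648. For single genes limma called 0 of 9830 (56 at an unadjusted p under 0.05, 422 with slide as a fixed block, 491.5 expected by chance). TMCC2 (−1.96 ± 0.36), JAKMIP3 (−1.72 ± 0.40) and CDSN (−0.60 ± 0.21) had the smallest p.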

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

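The splits of the arrays and the check for single arrays that stand apart were planned, while the other tests of the 3 patterns below were chosen after the results had been seen.

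The most visible pattern was the difference between the 2 slides of 0 Gy arrays, on which 6827 of 9806 genes differed. Weak signal on the dim slide would concentrate it in faint probes. Its SD among the brightest probes was 103% of that over all probes, so it was not confined to faint ones. The common floor narrows the differences of faint probes, so this ratio cannot show how much weak signal adds there. GC content of the probes accounted for little of it (correlation −0.205 across probes). The differences of paired probes of a gene correlated at 0.223 (95% interval 0.176 to 0.269, 1580 genes), above 0 but below the 0.474 of the probes' levels, which neither excludes nor establishes a change in whole genes. Labelling, hybridisation and scanning of the slides were not tested, and cultures that differed between the slides stay open.

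The genes called between the doses were weighed against slide differences alone. Simulated slide effects with no dose effect called 1690 to 1865 genes over both distances in 10 runs, more than the 1026 observed. The simulation gave all slides of a gene 1 common spread, which includes any dose difference. The measured differences had an SD of 1.27 between the 0 Gy slides and 0.22 between the 0.5 Gy slides. The simulated slides are unlike the measured ones in this, so the counts leave open whether differences between slides are enough. With slide as a random block these simulations still called 132 to 240 genes, so the 2 genes called with that block, SKP1 and LMNB2, are not thereby free of slide effects. Of the other probes of the called genes 73.2% had the sign of the called probe (183 of 250), which decides neither way. With 2 slides per dose the spread between slides is estimated only weakly. Slide means counted once per distance gave 0 genes in limma (985 at an unadjusted p under 0.05), with each slide entering by 2 means. Slide differences and a response of bystander tissue to the dose therefore both stay open for single calls.

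The lists that differed between distances at 0.5 Gy were weighed on the cornified envelope list. No array by itself carried it (highest adjusted p without 1 array 3.03e-04), nor did 1 slide (the smaller difference of the list mean was −0.19), and adjusting for probe GC left it called (adjusted p 2.30e-08). A smaller share of differentiating layers in the far pieces stays open, since the suprabasal mean differed by 0.00497 over members that went both ways, with near arrays from 0.05 to 0.31, and the basal list mean was 0.14 and 0.12 higher in the far pieces on the 2 slides. A response that declines with distance stays open too, as does the way the strips were taken from the tissue. The calls rest mostly on a preset correlation between genes, so the pattern is a hypothesis.

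Other splits of the same arrays bear on whether chance can be excluded, although they treat arrays of 1 slide as exchangeable. For the near strip 1 of 35 splits, the real one, gave as many genes (183, highest other 0), and likewise 1 of 35 at the far strip (115, highest other 0), so chance can be excluded as far as arrays are exchangeable, while keeping the slides whole leaves only 3 splits, too few for a share under 0.05. The same simulated slide effects, with 1 spread for all slides that includes any dose difference, called 500 to 664 genes near and 563 to 693 far. These counts lie above the real ones, under the same limit. Over both distances 3 of 100 splits gave as many as the real 1026, the highest other 2227. Parting slides 1 and 2 from slides 3 and 4 gave 1387 and parting slides 1 and 4 from slides 2 and 3 gave 3002, which points to a structure by slide. Slide means counted once per distance gave 0 (985 at an unadjusted p under 0.05 in limma). Chance cannot be excluded for the lists shifted with dose, where 6 of 35 splits gave as many at the near strip (real 1, highest other 4) and 37 of 100 over both distances (real 1, highest other 3).

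Where the real count was 0, every split gives as many, so the splits say nothing about chance. This holds for lists at the far strip (35 of 35 splits, highest other 2), for genes in the interaction (100 of 100, highest other 5673), for genes (35 of 35, highest other 6842) and lists (35 of 35, highest other 2) between distances at 0 Gy, and for genes between distances at 0.5 Gy (35 of 35, highest other 0). The high gene counts of other splits point to a structure of the arrays, and the 2 slides of 0 Gy arrays alone differed in 6827 genes. For lists between distances, adjusted within each contrast, 1 of 35 splits gave as many at 0.5 Gy (real 5, highest other 4) and 1 of 100 for the interaction (real 5, highest other 4). Chance can be excluded for these 2 counts only as far as arrays are exchangeable between slides, by a margin of 1 list and at the preset correlation. Splits within the 2 slides of 0.5 Gy are too few for a share under 0.05, and splits for the interaction also carry the difference between the 0 Gy slides. Chance cannot be excluded for any single list. The exact permutation p of the lists called at 0.5 Gy was 0.357 after adjustment. That test cannot decide, since with a smallest possible p of 0.0286 a list by itself could not pass the adjustment. Over all 3 distance contrasts, the lists whose dose effect differed between distances were mitosis (0.38), DNA replication (0.21), cornified envelope (−0.20) and ribosomal proteins (0.14), and the other list counted among the 5 was that of wound keratins and alarmins (−0.18, adjusted p 0.0713 over all 3 contrasts).

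Single arrays stood apart from the other 3 of their group in 51 of 672 groups of values tested (7.59%), where chance gives about 1 in 20. On 0 Gy near replicate 3 the SD of repeated spots was 0.395 (others 0.125 to 0.138), the inflammatory cytokine list had a mean of −1.14 (others −0.16 to 0.01) and the wound list one of −1.15 (−0.18 to −0.05). The log2 level of GJA1 was −2.98 there (others 1.74 to 2.06), PRR7 −4.60 (−0.72 to −0.45), AKR1C1 0.38, CDC45 −3.59, DCN −4.60, EGR2 −0.36, ISG15 −3.26, PFKL −3.72, SAMD9 −4.60 and SLC25A36 −4.16. On 0 Gy near replicate 4 the levels were −4.24 for COL6A1, −2.55 for EGLN3, −4.08 for FGD4 and −0.0302 for THY1 (others −2.73 to −2.50). On 0 Gy far replicate 3 they were −2.45 for CCN1, −3.53 for FGD4, 1.52 for MACF1 (others −1.64 to −1.17), −1.81 for RABEP1 and −4.23 for SLC25A36. On 0 Gy far replicate 4 the repair list had a mean of −0.16 (others 0.19 to 0.20) and the endothelial list −0.28 (0.22 to 0.25), with GJA1 at 1.79, ISG15 at −3.16, KAT2B at −3.64 and XRCC6 at −0.11 (2.41 to 2.82).

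At 0.5 Gy, near replicate 1 stood apart for AKAP11 (−1.60), JUNB (1.65), MACF1 (0.91), MITF (−3.02), OIP5 (−4.48) and XRCC6 (2.25). Near replicate 2 did so for the hypoxia list (mean 0.20, others 0.02 to 0.03), CCNB1 (−3.03), CCNG1 (−2.61) and CDH3 (−0.90), and near replicate 4 for BBC3 (2.09), CDK1 (−4.31), CXCL5 (−2.07) and RPS18 (4.56). Far replicate 1 did so for CCNB1 (−3.46), KLHL17 (−4.35) and LORICRIN (6.66), far replicate 2 for the p53 list (mean 0.13, others −0.02 to 0.00) and ANO8 (−1.85), and far replicate 3 for CCN1 (−3.41), MT2A (−0.67), STRAP (−0.70, others −0.19 to −0.12) and TGM1 (2.17).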

How the results depend on the processing

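Scaling over all probes, the lowest floor, slide means, leaving out a 0 Gy slide, slide as a fixed block for lists, tissue as a fixed block and leaving out 2 arrays were added after seeing the data. Counts are given for near, far and both distances, and the cause was not tested unless stated. They were 0, 0 and 0 with normexp, 96, 47 and 549 with quantile normalization, 2, 2 and 2 with slide as a random block, 106, 41 and 132 with tissue as a random block, 30, 21 and 432 with the series table, 67, 34 and 415 with scaling over all probes, 49, 32 and 605 with the lowest floor, and 0, 0 and 0 with slide means counted once, which leaves fewer samples. They were 4524, 4831 and 6036 in replicates 1 and 2, 1858, 1593 and 3633 in replicates 3 and 4, 4928, 5201 and 6394 without the dim and 3987, 2621 and 5011 without the bright 0 Gy slide. The pair of slides as a fixed block gave 333 near and 240 far, only the arrays compared 6 and 12, and the array median 69 far. Filters, the choice of probe and an intensity trend kept each dose count within 1.5 times.

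Genes differing between distances at 0.5 Gy numbered 1 with slide as a random block, 20 in replicates 1 and 2 and 2 with tissue as a random block. The interaction gave 2 in replicates 1 and 2 and 2 with tissue as a random block, while all other settings gave 0. Lists shifted with dose numbered 2, against 18 with normexp, 0 over probes well above background on all arrays, 1 with slide as a random block, 7 in replicates 1 and 2, 6 in replicates 3 and 4, 4 with the series table, 6 without the bright slide and 0 with an estimated correlation. Lists shifted between distances numbered 9, against 33 with normexp, 5 in replicates 1 and 2, 5 with the lowest floor and 2 with an estimated correlation. Leaving out 1 array gave 59 to 249 near, 25 to 266 far, 658 to 1438 over both, 0 to 0 for the interaction and both distance counts, 2 to 2 lists with dose and 6 to 9 between distances.

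The numbers of the replicates did not pair the arrays, so the tissue block, which rests on these numbers, is not borne out. Same-numbered arrays correlated at −0.24 to −0.02 between doses and at −0.23 to −0.005 between distances at 0.5 Gy, with none best with its own number, and at 0.40 to 0.87 at 0 Gy, where 1 of 4 was best with its own number and slide mates correlated at 0.68 to 0.90. The replicate block gave 134, 68 and 1028 genes for dose and 0 for the interaction and for distance at either dose.

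With normexp, 142 of the 183 near, 110 of the 115 far and 713 of the 1026 calls over both distances kept their sign. The normexp offset lifts faint genes on slide 3, which may add to its list counts and to the reversals below. Among the genes of the naming rule and the lists, the sign of a gene's difference or the direction of a list's test reversed in 40 cases. With normexp they were −0.29 for CCNG1, −0.0739 for TRIAP1, −0.13 for CXCL5, −0.0268 for ID2 and −0.0118 for HRK. For lists the median with normexp was 0.58 (ribosomal, near), 0.21 (cornified, far), 0.10, 0.12 and −0.16 (heat shock, immediate early and ribosomal, interaction) and −0.0406, −0.0733, 0.28 and 0.00201 (heat shock, immediate early, ribosomal and hypoxia, distance at 0 Gy). Replicates 1 and 2 gave 0.74 for NBN, −0.33 for OASL, 1.79 for CD79A, 0.36 for CDKN1A, 1.62, 2.02 and 1.82 for the immune list (near, far, both) and 0.0887 for immediate early genes (distance at 0 Gy). Without the dim slide NBN was 0.51, OASL −0.29, CD79A 1.67 and CDKN1A 0.33. Replicates 3 and 4 gave −0.50 for UBE2C, 0.53 for NDRG1, −0.81 for PMEL, −0.76 for COL6A3, −1.60 for CD3E, −1.23 for KRT1 and −1.98 for KRT10. Without the bright slide PMEL was −0.73, COL6A3 −0.65, CD3E −1.48, KRT1 −1.09 and KRT10 −1.81. Quantile normalization gave −0.34 for ASPRV1 (far) and the mean of probes 0.64 for HK2. Among the named genes over both distances, 3540 of the other comparisons stayed on their side of the threshold, 470 lost and 184 gained a call. Signal limits these results, since 21.1% to 28.6% of probes were well above background on slide 3.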

Other observations

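The tests below were chosen after the results had been seen. Gene groups were set against the difference of the 0 Gy slides, bright minus dim, by medians and counts of called genes, with no list test. Of cornified envelope genes 18 of 32 were lower on the bright slide and 9 higher (median −0.70), of cholesterol synthesis genes 15 of 22 were higher and 1 lower (1.07), of gap junction genes 5 of 6 were higher (1.32) and of p53 targets 13 of 21 were higher and 2 lower (0.73). KRT10 ranged from 5.28 on the bright to 8.98 on the dim slide, with 7.34 and 6.99 on the 0.5 Gy slides, and KRT1 from 5.60 to 8.43, with 7.49 and 7.22. These are values of 2 slides of sham tissue.

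TMCC2 and JAKMIP3 had the smallest p for distance at 0.5 Gy and for the interaction without passing. Their dose differences were 1.65 ± 0.26 and 1.56 ± 0.28 at the near strip and −0.31 ± 0.26 and −0.16 ± 0.28 at the far strip, and OIP5, a centromere protein gene, ran the other way (0.17 ± 0.29 near, 1.11 ± 0.29 far). Matrix protease genes were higher in the far strip at 0.5 Gy on both slides (0.26 and 0.13) and hypoxia genes lower (−0.14 and −0.08), each with a two-sided exact permutation p of 0.0286 and an adjusted p of 0.357.

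Different probes of a gene gave dose differences that correlated at 0.209 across genes, against 0.474 for their levels, and differences between distances at 0.5 Gy that correlated at 0.259.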
